A study of Homo sapiens with 12 samples.

How the data were processed

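Total RNA was isolated with a Qiagen column kit and turned into libraries with an Illumina RNA kit, per the labels' protocols, from 2 human liver cancer cell lines: FOCUS and Huh7. The labels give 4 groups of 3 libraries: FOCUS-GFP, FOCUS-shFzd2, Huh7 WT and Huh7 Fzd2 OE. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.1.0, Picard, HTSeq 0.6.0 and the human genome build hg38. The settings of these tools, the gene annotation and the strand setting are not given in the sources used here. The table deposited by the authors holds whole-number read counts per gene symbol, not normalized, for 26485 genes, of which 5029 had no read in any library. A further 5 rows are HTSeq summary rows. They stayed out of library sizes and tests. Their largest member, reads aligned to more than 1 place, took between 11.03% and 17.95% of all counted reads per library, and reads in no annotated gene took between 7.05% and 11.4%.

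The deposited table has 12 columns. The names of 6 columns give their group by the terms GFP or Fzd2OE. The other 6 were matched by elimination: columns named FOCUS without GFP were read as FOCUS-shFzd2, and columns named Huh7LUT as Huh7 WT, since the term LUT is not explained by the labels. Every statement on FOCUS-shFzd2 and Huh7 WT rests on this reading, and groups are therefore written as libraries labelled with their group name. Of the gene symbols, 23900 (90.2%) matched a gene of GENCODE release 29, which was used only for positions.

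Each comparison was fitted alone on its 6 libraries with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter on low counts, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes come from this test. Genes that passed are said to have risen or fallen in the group named first. The comparisons were FOCUS-shFzd2 against FOCUS-GFP, Huh7 Fzd2 OE against Huh7 WT, and FOCUS-GFP against Huh7 WT. The difference between the effects of more against less FZD2 in the 2 lines was tested as an interaction in 1 fit of all 12 libraries. Another comparison, Huh7 Fzd2 OE against FOCUS-shFzd2, was added after the data were seen. Folds come from the fit of each comparison, with scaling factors of its own, and can differ from the ratio of the levels printed. Levels are means ± SD over 3 libraries in normalized CPM, that is, CPM of gene reads after TMM scaling over all 12 libraries. The factors of that scaling were between 0.838 and 0.89 in the libraries labelled FOCUS-GFP and Huh7 WT and between 1.14 and 1.17 in the others, so scaling by library size alone was added after seeing the data.

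A fold against a group with no read was computed against a floor of 3 counts over the group and is given as a lower bound. With 1 to 3 counts the ratio is given with its 95% counting interval. The floors were 0.0365, 0.0324, 0.0652 and 0.0453 normalized CPM for the groups labelled FOCUS-GFP, FOCUS-shFzd2, Huh7 WT and Huh7 Fzd2 OE. Intervals and floors cover counting error only.

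There were 32 gene lists, written from textbook knowledge before the data were examined, as were the tests and the rule for naming genes. They cover Wnt branches, epithelial and mesenchymal genes, liver genes, other developmental pathways, proliferation, stress, interferon and markers of other cell types. The list of mitochondrially encoded genes had 0 members among the genes of the table and was not tested. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were the alternatives. Some genes belong to more than 1 list. The rule named FZD2, the 10 largest rises and 10 largest falls among genes that passed with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups (clone-based names left out), up to 4 members per list, and 6 genes per pattern of directions shared by knockdown and overexpression. XIST, TSIX and Y-linked genes were left out of naming, and some other genes that the rule selects are not named.

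On simulated counts, the edgeR step recovered 67 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold in the knockdown simulation over 15175 genes, and 8.84% of its calls were unchanged genes. The same 100% was recovered in the overexpression simulation over 14798 genes, with a share of unchanged genes of 4.26%, and in the comparison of control lines over 14892 genes, with a share of 8.13%. Each simulation changed 200 genes and a list of 30 and left all others equal. Most genes passed in the data, so the scaling was not tested in a setting like theirs. Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, other filters, a test against a fold of 1.5, the replicate number as a block, 1 fit of all libraries, and each library left out in turn.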

Results

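Gene expression was measured by RNA sequencing of total RNA in 12 libraries from the human hepatocellular carcinoma lines FOCUS, labelled mesenchymal, and Huh7, labelled epithelial. FZD2 encodes a Frizzled receptor for Wnt ligands. It was knocked down in FOCUS cells (shFzd2, with GFP libraries as controls) and overexpressed in Huh7 cells (Fzd2 OE, with WT libraries as controls), with 3 libraries per group. Reads counted in genes came to 30.8, 28.5 and 33.5 M in the libraries labelled FOCUS-GFP and to 27.1, 30.1 and 23.6 M in those labelled FOCUS-shFzd2. They came to 19.8, 20.2 and 14.6 M in those labelled Huh7 WT and to 18.2, 18.5 and 20.2 M in those labelled Huh7 Fzd2 OE. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

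Libraries of 1 group were close to each other: Pearson r across genes of log2(CPM + 1) lay between 0.9988 and 0.9994. Chi-square per degree of freedom against counting noise ran from 1.19 to 5.19 between libraries of a group, which does not tell separate cultures from repeat preparations. Between groups, the libraries labelled Huh7 Fzd2 OE were closest to those labelled FOCUS-shFzd2, with r from 0.9952 to 0.996. Their r with the libraries labelled Huh7 WT was 0.882 to 0.8834. The libraries labelled FOCUS-GFP and FOCUS-shFzd2 had r from 0.922 to 0.9232. Genes that passed the edgeR quasi-likelihood test with a fold of at least 10 numbered 13 between Huh7 Fzd2 OE and FOCUS-shFzd2, 1798 between FOCUS-shFzd2 and FOCUS-GFP, 2699 between Huh7 Fzd2 OE and Huh7 WT, and 2705 between FOCUS-GFP and Huh7 WT. The levels of FZD2 followed all 4 labels in direction, which does not show the cell line of a library. Every direction given for a group is that of the libraries labelled with its name.

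**Figure D1:**
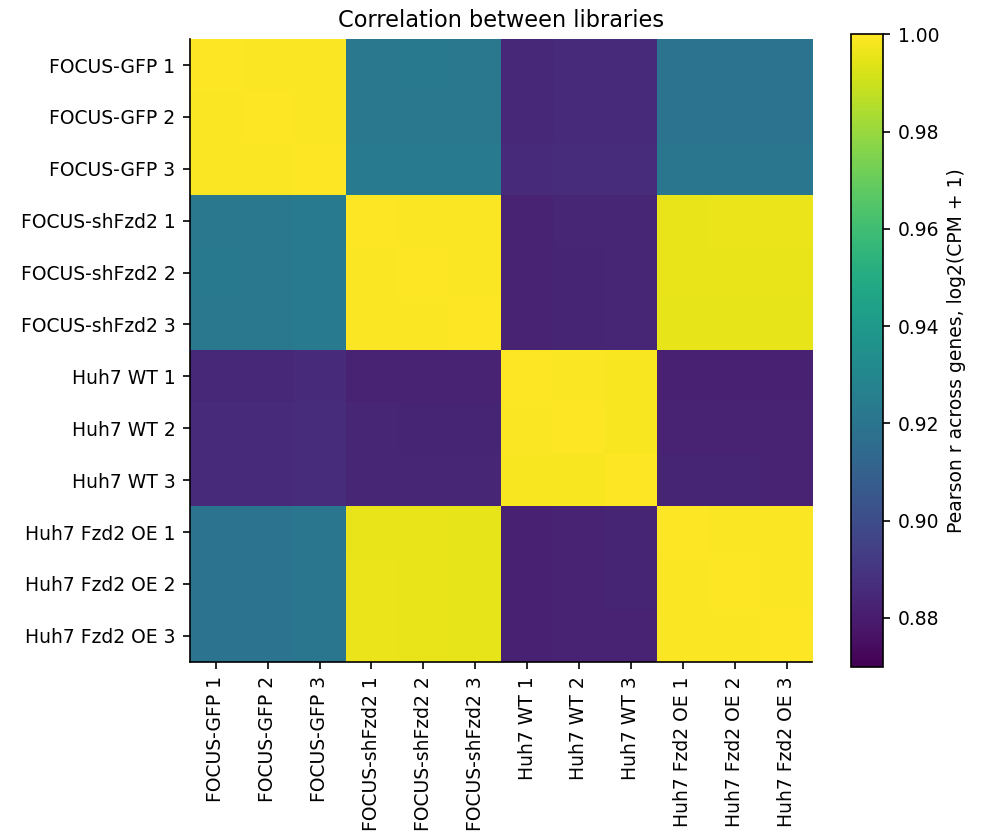
Pearson correlation across genes of log2(CPM + 1) between the 12 libraries, with the replicate number after the group name and r as colour. The libraries labelled FOCUS-shFzd2 and Huh7 Fzd2 OE form 1 block with r between 0.9952 and 0.996 across the groups.

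FZD2 was checked first in every library. The gene lies on chromosome 17 from 44557459 to 44559570 (hg38, plus strand), has 1 exon, and overlaps 0 other annotated genes (ENSG00000180340.6). FZD2 stood at 102, 103 and 105 normalized CPM in the libraries labelled FOCUS-GFP and at 6.59, 6.3 and 6.96 in those labelled FOCUS-shFzd2. In the fit of the FOCUS-labelled libraries FZD2 had a log2 change of -3.96 ± 0.0538 (SE), a 15.5-fold fall (adjusted p 5.41e-23). By itself this fall does not show a knockdown, since a different cell line in the libraries labelled FOCUS-shFzd2 was not excluded. In the libraries labelled Huh7 WT FZD2 stood at 2.23, 2.78 and 2.64, and in those labelled Huh7 Fzd2 OE at 1313, 1295 and 1318. In the fit of the Huh7-labelled libraries, which has its own scaling factors, FZD2 rose 553-fold (log2 9.11 ± 0.056, SE, adjusted p 4.69e-34). The counts do not tell reads of an introduced FZD2 copy from those of the endogenous gene.

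**Figure D2:**
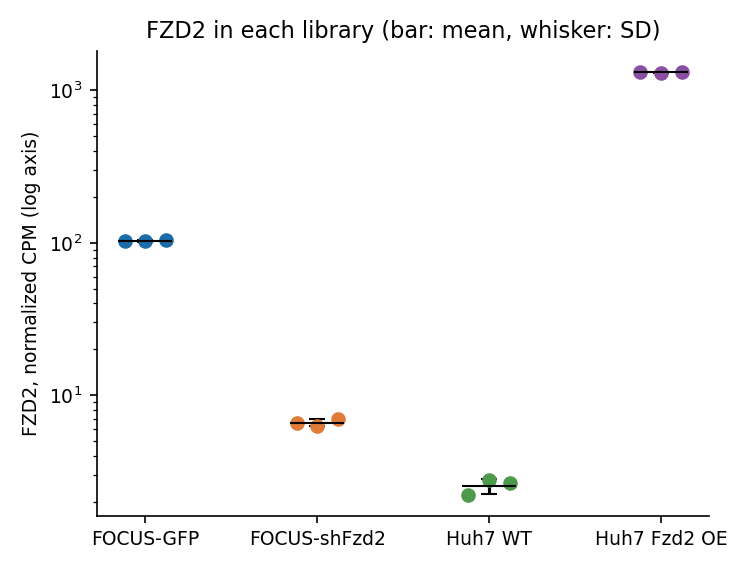
FZD2 in normalized CPM on a log axis for the 12 libraries in 4 groups (points), with the group mean (bar) and SD (whisker). FZD2 lay near 103 in FOCUS-GFP, 6.61 in FOCUS-shFzd2, 2.55 in Huh7 WT and 1309 in Huh7 Fzd2 OE.

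The comparison of libraries labelled FOCUS-shFzd2 with those labelled FOCUS-GFP asked which genes change when FZD2 is reduced in mesenchymal-type liver cancer cells. TGFBI, a matrix protein induced by TGF-beta, stood at 0.265 ± 0.0807 normalized CPM in the libraries labelled FOCUS-shFzd2 against 759 ± 3.74 (SD, n = 3 per group). The receptor tyrosine kinase AXL stood at 0.513 ± 0.159 against 719 ± 52.7. The epithelial keratin KRT7 was also lower, at 0.435 ± 0.0816 against 1599 ± 46.3. Among genes that rose, the growth factor MDK (midkine) went from 5.56 ± 0.755 to 117 ± 5.84, the protocadherin PCDH10 from 4.19 ± 0.438 to 104.5 ± 3.37, and CPS1, which catalyses the first step of the urea cycle, from 3.06 ± 0.141 to 59.5 ± 2.74.

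Of 15175 genes tested, 13443 passed, of which 6663 rose and 6780 fell. A change of at least 2-fold was seen in 6379 of these genes. By fitted log2 change, which depends on the prior count for genes with 0 reads, the 10 largest falls were genes with 0 reads in the libraries labelled FOCUS-shFzd2. KRT7, which had reads in both groups, fell 3649-fold. The genes with 0 reads were C4BPB, a chain of the complement inhibitor C4BP, at least 1868-fold lower than 60.4 ± 0.801, TM4SF1 (at least 1859-fold), FLG, PLEK2, SFTA1P, TNNT2, SLFN12, CASP4, SLC1A7 and BIRC7 (at least 718-fold). The largest rise was that of ADGRB1, an adhesion receptor, from 0.268 ± 0.0537 to 19.4 ± 1.56, or 71.6-fold (adjusted p 1.88e-18). NPNT, FBXL16, SHISA2, CYP26A1, FREM2 and NYNRIN rose between 18.6-fold and 29.5-fold. With FZD2, XIST, TSIX and Y-linked genes left out, 1093 genes passed and were 10-fold or more lower in these libraries than in those labelled FOCUS-GFP. Of these, 1028 (94.1%) were also 10-fold or more lower in the libraries labelled Huh7 Fzd2 OE, where FZD2 is high. In those labelled Huh7 WT, 628 (57.5%) were.

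In the libraries labelled FOCUS-shFzd2, of 30 YAP and TAZ target genes, 27 fell and 3 rose (camera adjusted p = 2.81e-06, adjusted p = 0.21 with an estimated correlation). IGFBP3, which binds insulin-like growth factors, fell 645-fold and tissue factor (F3) 154-fold. Of 20 NF-kB and cytokine genes, 19 fell and 1 rose (adjusted p = 0.00021, adjusted p = 0.187 with an estimated correlation), among them the adhesion receptor ICAM1 (419-fold) and the cytokine IL32 (150-fold). Of 35 interferon response genes, 27 fell and 4 rose (adjusted p = 0.000763, adjusted p = 0.187 with an estimated correlation). The GTPase MX2 went from 35.2 to 0.022 normalized CPM, a ratio with a counting interval of 452 to 13500. Of 18 STAT3 target genes, 15 fell and 3 rose (adjusted p = 0.00439, adjusted p = 0.187 with an estimated correlation), with the oncostatin M receptor gene OSMR 90-fold lower. SAA1 and SAA2 share reads and are uncertain. Of 32 immediate early genes, 21 fell and 9 rose (adjusted p = 0.0287, adjusted p = 0.21 with an estimated correlation), FOSL1 by 90.2-fold. Of 18 heat shock genes, 16 fell and 2 rose (adjusted p = 0.00166, adjusted p = 0.187 with an estimated correlation). The chaperone HSPB8 fell 78.4-fold, and HSPA1A, which shares reads with HSPA1B, is uncertain.

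In the libraries labelled FOCUS-shFzd2, of 38 collagens and matrix genes, 30 fell and 7 rose (camera adjusted p = 0.000923, adjusted p = 0.303 with an estimated correlation). THBS1 (thrombospondin 1) went from 202 ± 6.81 to 0.26 ± 0.0275 and COL12A1 from 279 ± 30.9 to 1.33 ± 0.497. Of 26 matrix proteases and inhibitors, 19 fell and 7 rose (adjusted p = 0.00751, adjusted p = 0.21 with an estimated correlation), including the membrane-bound protease MMP14 (231-fold) and ADAM12 (548-fold). Of 32 integrins and focal adhesion genes, 23 fell and 7 rose (adjusted p = 0.00751, adjusted p = 0.383 with an estimated correlation), with ITGA3 67.1-fold lower. Of 31 mesenchymal genes, 22 fell and 8 rose (adjusted p = 0.00993, adjusted p = 0.21 with an estimated correlation). Of 30 epithelial genes, 16 fell and 13 rose, and the list did not pass (adjusted p = 0.6).

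Of 15 Hedgehog pathway genes, 11 rose and 1 fell (camera adjusted p = 0.00993, adjusted p = 0.21 with an estimated correlation), such as KIF7, a ciliary kinesin (8.96-fold), and GAS1 (8.11-fold). Of 24 beta-catenin target genes, 18 rose and 5 fell (adjusted p = 0.0165, adjusted p = 0.21 with an estimated correlation). RNF43, which removes Frizzled receptors from the surface, rose 16.5-fold, while CD44 fell 674-fold and DKK1, a secreted Wnt antagonist, 170-fold. Of 11 Frizzled receptors, 8 rose and 2 fell, FZD2 among the latter, and the list did not pass (adjusted p = 0.166, 0.0565 without FZD2). FZD9 rose 5.04-fold, and SMO, a relative of the Frizzled receptors that acts in the Hedgehog pathway, 4.01-fold. Of 12 Wnt ligands, 8 rose and 4 fell (adjusted p = 0.341), with WNT11 up 11-fold. Non-canonical Wnt components moved both ways, 17 up and 18 down of 38 (adjusted p = 0.937), with NFATC2 13.3-fold lower and NFATC1 10.5-fold higher. Of 26 Notch pathway genes, 15 rose and 10 fell (adjusted p = 0.134), with NOTCH3 up 12.5-fold. Of 30 TGF-beta target genes, 18 fell and 12 rose (adjusted p = 0.369), with INHBA 41.1-fold lower.

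Scaling by library size alone moves all genes alike, so turns in the counts under it do not set a list apart from other genes. Of 36 G2/M genes, 25 fell and 5 rose (camera adjusted p = 0.00993, adjusted p = 0.279 with an estimated correlation), with ANLN (anillin) 5.65-fold lower, but scaled by library size alone 18 rose and 15 fell. Of 57 ribosomal protein genes, whose reads can be shared with pseudogenes, 38 fell and 16 rose (adjusted p = 0.0219, adjusted p = 0.744 with an estimated correlation), and 27 rose and 24 fell under that scaling. Of 45 DNA replication genes, 28 rose and 17 fell (adjusted p = 0.341), with TYMS 2.99-fold lower and RPA2 2.79-fold higher. Of 26 p53 target genes, 18 rose and 6 fell (adjusted p = 0.141), with SESN2 up 4.31-fold. Stress response genes moved both ways, 13 up and 17 down of 33 (adjusted p = 0.764, 18 up and 12 down by library size alone), with PHGDH 4.46-fold higher. Of 27 cholesterol synthesis genes, 11 rose and 14 fell (adjusted p = 0.596, 14 up and 12 down by library size alone), with FADS1 11.6-fold lower. Of 33 hypoxia and glycolysis genes, 13 rose and 17 fell (adjusted p = 0.743, 19 up and 11 down by library size alone), with ADM 31.6-fold lower. Of 7 histone genes, which share reads among copies, 3 rose and 4 fell (adjusted p = 0.743, 3 up and 2 down by library size alone).

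Liver genes were few in the knockdown comparison: 11 of 45 hepatocyte genes could be tested, of which 3 rose and 6 fell (adjusted p = 0.596, 4 up and 4 down by library size alone). APOE fell 14.6-fold. Of 15 liver transcription factors, 10 rose and 4 fell (adjusted p = 0.141), with FOXA1 up 13.5-fold and CREB3L3 20.2-fold lower. Markers of other cell types were among the genes that fell. Of 10 endothelial markers, 6 fell and 4 rose (adjusted p = 0.422), and the endoglin gene ENG went from 134 ± 2.77 to 0.474 ± 0.162. Of 6 leukocyte markers, 4 fell and 2 rose (adjusted p = 0.458), with CD68 107-fold lower. Stellate cell and fibroblast markers split evenly, 6 up and 6 down of 12 (adjusted p = 0.832), with PDGFRB 138-fold and POSTN 131-fold lower.

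Adjusted over the list alone, the counts of the knockdown comparison were the same except that 18 hypoxia genes fell and 17 ribosomal protein genes rose. In all, 2 lists rose and 12 fell of 31 tested. With an estimated correlation camera called 0 lists, with 6 at an unadjusted p under 0.05, while fry called 30. Scaled by library size alone, an alternative added after seeing the data, the median log2 change moved from -0.00439 to 0.36, with 8817 genes up and 4820 down. No strand was stated, so reads of antisense partners cannot be separated.

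The comparison of libraries labelled Huh7 Fzd2 OE with those labelled Huh7 WT asked which genes change when FZD2 is raised in epithelial-type liver cancer cells. AFP, alpha-fetoprotein, stood at 0.213 ± 0.0583 normalized CPM in the libraries labelled Huh7 Fzd2 OE against 9913 ± 123 in those labelled Huh7 WT (SD, n = 3 per group). SERPINA1, which encodes alpha-1 antitrypsin, had 0 reads against 2253 ± 91.4, at least 49920-fold lower. APOB, the main protein of low-density lipoprotein, had 2 reads against 2930 ± 207 normalized CPM, a ratio with a counting interval of 26700 to 795000. Transcripts that rose included the neuronal kinesin KIF1A, from 0.0197 ± 0.0341 to 265 ± 2.71 (ratio interval 2190 to 481000), the neurofilament gene NEFM, from 0.0197 ± 0.0341 to 218 ± 1.84, and WNT5A, a non-canonical Wnt ligand, from 0 reads to 47.4 ± 1.9 (at least 726-fold). In the libraries labelled FOCUS-shFzd2, KIF1A stood at 210.3 and AFP was among the genes with too few reads to be tested.

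Of 14798 genes tested, 13162 passed, of which 6897 rose and 6265 fell, and 6796 changed at least 2-fold. By fitted log2 change, which depends on the prior count for genes with 0 reads, the 10 largest falls were those of SERPINA1, APOB, AFP, AMBP, FGA, ITIH2, FABP1, ASGR2, TSPAN8 and VIL1 (at least 4939-fold). The largest rises included the protease inhibitor gene TIMP1 (at least 974-fold), RIMS4, PJA1, MAGED1, the cyclin gene CCND2, SH3BGRL and CELF2 (at least 614.5-fold). These genes were also present in the libraries labelled FOCUS-shFzd2, where FZD2 is low. TIMP1 stood at 61.49 normalized CPM there against 63.55 in Huh7 Fzd2 OE, and MAGED1 at 242.7 against 193.7. Their rises therefore mark a lack of reads in Huh7 WT and are not particular to high FZD2. Of the 2699 genes 10-fold or more apart in this comparison, 2436 (90.3%) lay within 2-fold between the libraries labelled Huh7 Fzd2 OE and FOCUS-shFzd2.

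Liver identity genes fell as groups in the libraries labelled Huh7 Fzd2 OE. Of 38 hepatocyte genes, 36 fell and 1 rose (camera adjusted p = 1.87e-11, adjusted p = 0.0698 with an estimated correlation). Their median log2 change was -12.5, or -11.6 with bounds in place of fits for genes with no read in a group. All 22 liver transcription factors fell (adjusted p = 9.36e-08, adjusted p = 0.0698 with an estimated correlation). HNF4A, a nuclear receptor of hepatocytes, went from 416 ± 11.7 to 0.0312 ± 0.027 (ratio interval 3820 to 114000), and the bile acid receptor gene NR1H4 from 126 ± 1.99 to 0.0299 ± 0.026. Of 32 epithelial genes, 28 fell and 3 rose (adjusted p = 9.1e-07, adjusted p = 0.0698 with an estimated correlation), among them KRT19 (at least 1822-fold) and the tight junction gene CLDN1, from 729 ± 8.77 to 2.88 ± 0.289. Of 28 STAT3 target genes, a list that holds acute phase proteins of the liver, 24 fell and 3 rose (adjusted p = 2.04e-06, adjusted p = 0.0787 with an estimated correlation), with haptoglobin (HP) at least 1718-fold lower. Of 28 cholesterol synthesis genes, 23 fell and 4 rose (adjusted p = 6.81e-05, adjusted p = 0.0698 with an estimated correlation). HMGCS1, an enzyme of the mevalonate pathway, fell 11.2-fold.

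Of 20 NF-kB and cytokine genes, 19 fell and 1 rose (camera adjusted p = 5.59e-05, adjusted p = 0.0865 with an estimated correlation), with the chemokine gene CXCL5 at least 2767-fold lower. Of 33 genes of the unfolded protein and integrated stress response, 27 fell and 4 rose (adjusted p = 9.87e-05, adjusted p = 0.199 with an estimated correlation), including XBP1 (8.06-fold) and NUPR1 (23.7-fold). Of 32 immediate early genes, 21 fell and 8 rose (adjusted p = 0.0258, adjusted p = 0.236 with an estimated correlation), with the ERK phosphatase gene DUSP6 135-fold lower. Of 57 ribosomal protein genes, 47 fell and 7 rose (adjusted p = 3.89e-05, adjusted p = 0.556 with an estimated correlation), RPS12 by 3.82-fold. Of 33 hypoxia and glycolysis genes, 21 fell and 7 rose (adjusted p = 0.0383, adjusted p = 0.556 with an estimated correlation), while scaled by library size alone 14 rose and 15 fell. The hexokinase gene HK1 rose 1614-fold.

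All 10 Wnt ligands tested rose (camera adjusted p = 0.00307, adjusted p = 0.197 with an estimated correlation), among them WNT3A (at least 102-fold) and WNT9A (at least 31.5-fold). Of 17 Hedgehog pathway genes, 14 rose and 2 fell (adjusted p = 0.00576, adjusted p = 0.154 with an estimated correlation), with the transcription factor genes GLI3 and GLI2 at least 574-fold and 298-fold higher. Of 26 p53 target genes, 21 rose and 4 fell (adjusted p = 0.00693, adjusted p = 0.12 with an estimated correlation), with the receptor gene EDA2R at least 129-fold higher. Of 24 Notch pathway genes, 18 rose and 6 fell (adjusted p = 0.0256, adjusted p = 0.223 with an estimated correlation), with HEY2 181-fold higher (counting interval 63.5 to 899).

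Of 29 mesenchymal genes, 15 rose and 13 fell, and the list did not pass (adjusted p = 0.883). The repressor gene ZEB2 was at least 565-fold and TWIST1 at least 242-fold higher. Of 38 non-canonical Wnt components, 20 rose and 14 fell (adjusted p = 0.354), with the WNT5A co-receptor genes ROR2 (at least 229-fold) and PTK7 (600-fold in the fit) higher. Of 10 Frizzled receptors, 6 rose, FZD2 among them, and 3 fell (adjusted p = 0.424, 0.664 without FZD2), with FZD8 16.4-fold higher and FZD5 6.83-fold lower. Of 26 beta-catenin target genes, 10 rose and 13 fell (adjusted p = 0.44, 14 up and 11 down by library size alone), with APCDD1 at least 49.6-fold higher. Of 32 collagens and matrix genes, 21 rose and 11 fell (adjusted p = 0.167), with COL5A1 at least 391-fold higher. Of 22 matrix proteases and inhibitors, 11 rose and 10 fell (adjusted p = 0.893), a list whose median was 0.31 while camera's direction was down. Of 31 integrins and focal adhesion genes, 11 rose and 19 fell (adjusted p = 0.155), with ITGB8 14.3-fold lower. Their median was -0.46 and their mean 0.09. Of 29 YAP and TAZ target genes, 10 rose and 19 fell (adjusted p = 0.0988), with CTGF 40.5-fold lower. TGF-beta target genes moved both ways, 12 up and 14 down of 29 (adjusted p = 0.63, 14 up and 12 down by library size alone), with ID1 59.1-fold lower.

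Of 36 G2/M genes, 14 rose and 19 fell (adjusted p = 0.627), while by library size alone 23 rose and 8 fell. Of 45 DNA replication genes, 24 rose and 16 fell (adjusted p = 0.312), with CHAF1B 2.92-fold higher. Heat shock genes moved both ways, 9 up and 7 down of 18 (adjusted p = 0.883). Of 28 interferon response genes, 10 rose and 14 fell (adjusted p = 0.262), with OAS1 at least 32.6-fold lower. Of 10 histone genes, 1 rose and 7 fell (adjusted p = 0.113). Of 6 leukocyte markers, 2 rose and 4 fell (adjusted p = 0.354), and lysozyme (LYZ) went from 371 ± 6.99 to 0.32 ± 0.0908. Of 9 stellate cell and fibroblast markers, 6 rose and 2 fell (adjusted p = 0.146), with RELN 471-fold lower. Fewer than 5 endothelial markers could be tested, of which 2 rose and 2 fell, PECAM1 by 936-fold.

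Adjusted over the list alone, the counts of the overexpression comparison were the same except that 7 stellate cell and fibroblast markers rose. In all, 4 lists rose and 10 fell of 30 tested. With an estimated correlation camera called 0 lists, with 8 at an unadjusted p under 0.05, while fry called 30. Scaled by library size alone, the median log2 change moved from 0.06 to 0.41, with 8756 genes up and 4579 down.

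**Figure D3:**
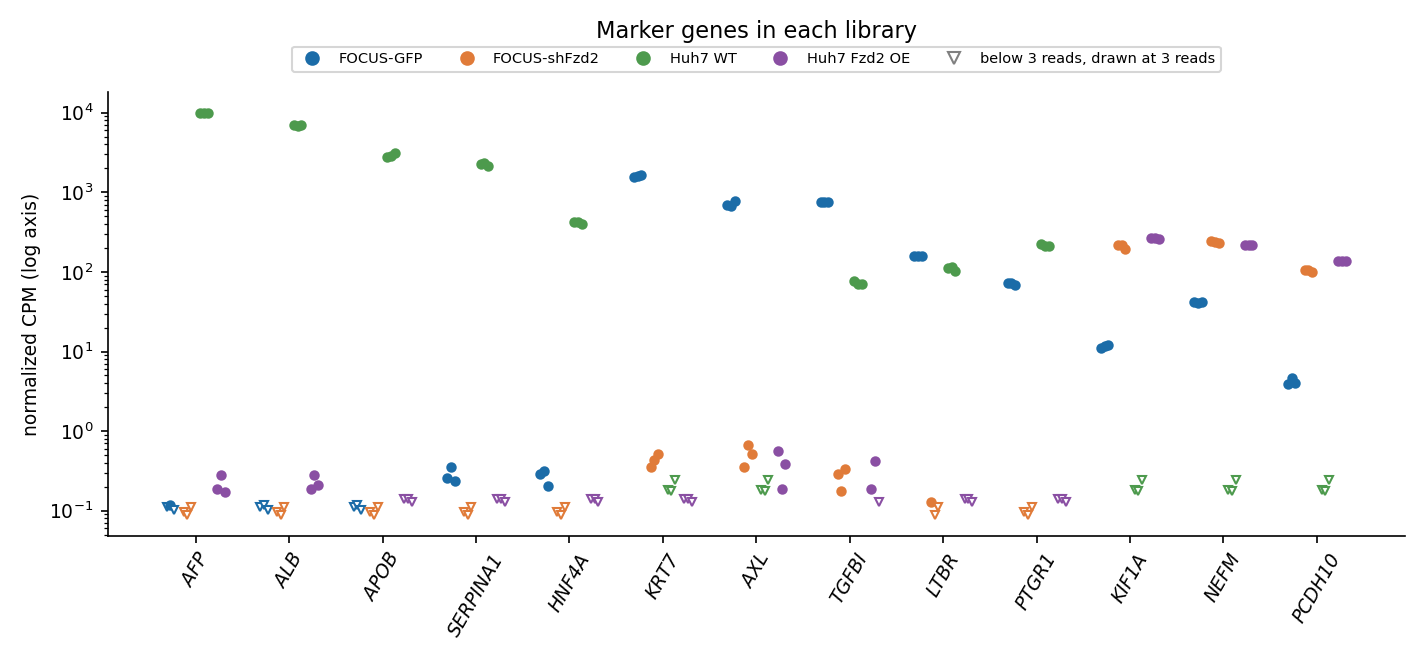
Normalized CPM on a log axis of 13 genes, chosen after their values were seen, in each of the 12 libraries, coloured by group, with open triangles at the level of 3 reads for libraries below it. AFP, at 9913 in Huh7 WT and 0.213 in Huh7 Fzd2 OE, and TGFBI, at 759 in FOCUS-GFP and 0.265 in FOCUS-shFzd2, show the pattern shared by FOCUS-shFzd2 and Huh7 Fzd2 OE.

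Setting both perturbations side by side asked whether genes follow FZD2, down when it is knocked down and up when it is overexpressed. Most did not. Of 14108 genes tested in both, 11181 passed in both, of which 7865 moved in the same direction and 3316 (29.7%) in opposite directions. Genes down with knockdown and up with overexpression numbered 1833, and those up with knockdown and down with overexpression 1483. Genes up in both numbered 4304, and genes down in both 3561. The libraries labelled FOCUS-shFzd2 and Huh7 Fzd2 OE were nearly alike (r from 0.9952 to 0.996), which by itself gives more genes of equal sign and a positive correlation, so these counts are not set against independent lists. Among genes changed at least 2-fold in both, 3029 went the same way and 663 opposite ways. Across 14107 genes, FZD2 left out, the log2 changes had Pearson r 0.521 and Spearman rho 0.464, and genes are not independent replicates.

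Genes whose signs followed FZD2 in both comparisons with the largest changes were ANKRD1, a YAP target (log2 -6.86 with knockdown and 5.02 with overexpression), BASP1, PCLO, the laminin genes LAMA1 and LAMA4, and the filamin gene FLNC. ANKRD1 stood at 728 in the libraries labelled FOCUS-GFP, 6.25 in FOCUS-shFzd2, 1.55 in Huh7 WT and 46.7 in Huh7 Fzd2 OE. FLNC stood at 913, 69.1, 3.29 and 79.7 in the same order. LAMA1 and PCLO were no higher in Huh7 Fzd2 OE (24.5 and 15.4) than in FOCUS-shFzd2 (26.3 and 17.8). LAMA4 (18 against 14.7) and FLNC differed little between these groups. The levels of these genes there lay between those of both control groups, which by itself gives opposite signs. ANKRD1 and BASP1 (38.4 against 13.8) were higher in Huh7 Fzd2 OE. Genes that went against FZD2 were GPC3, a heparan sulfate proteoglycan of liver tumours (log2 3.69 and -4.52), MBNL3, PLTP, SERPINF1, MGAT4A and PKDCC. GPC3 stood at 3.47, 44.2, 1279 and 51.8, so it differed little between FOCUS-shFzd2 and Huh7 Fzd2 OE. SERPINF1 was lower in Huh7 Fzd2 OE than in FOCUS-shFzd2 (17.7 against 42.8). Genes up in both were SHISA2, PCDH10, FREM2, NYNRIN, KIF1A and ZNF853, and genes down in both were PTGR1, SLCO1B3, LTBR, CASP4 and TM4SF1. The lymphotoxin beta receptor gene LTBR stood at 159 in FOCUS-GFP and 110.2 in Huh7 WT, against 0.0647 in FOCUS-shFzd2 and 0 in Huh7 Fzd2 OE.

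**Figure D4:**
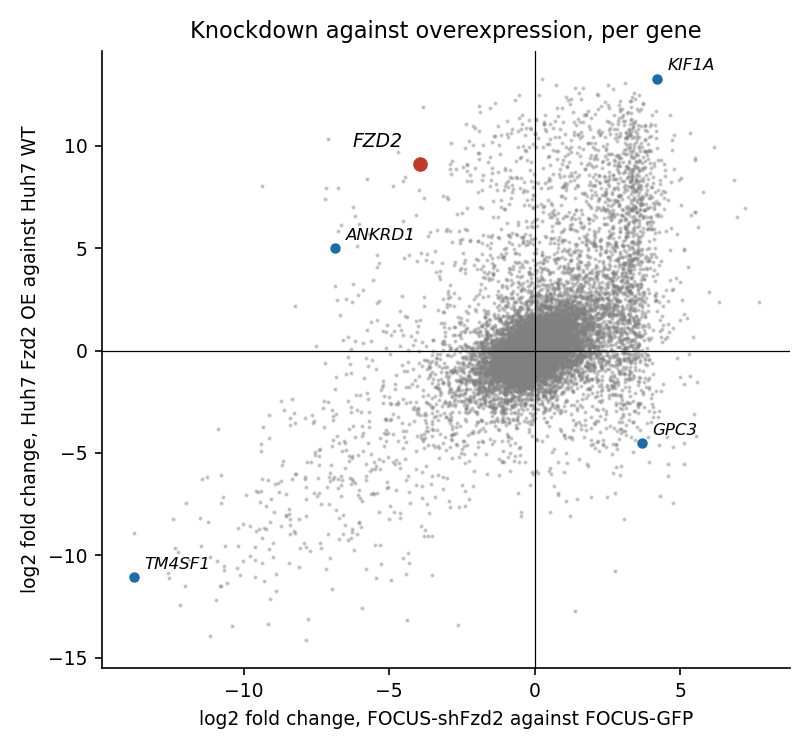
Log2 fold change of each gene tested in both fits, FOCUS-shFzd2 against FOCUS-GFP on the horizontal axis and Huh7 Fzd2 OE against Huh7 WT on the vertical axis, with named genes coloured. Of genes that passed in both, 7865 lie in the quadrants of equal sign and 3316 in those of opposite sign.

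The control libraries asked how the mesenchymal-labelled line differs from the epithelial-labelled line. ALB, serum albumin, had 2 reads in the libraries labelled FOCUS-GFP against 6996 ± 95.6 normalized CPM in those labelled Huh7 WT (ratio interval 79600 to 2370000), and transferrin (TF) had 1 read against 3077 ± 136. APOB and the retinol carrier RBP4 had 0 reads, at least 79780-fold and 42970-fold lower. Higher in the libraries labelled FOCUS-GFP were KRT7, at 1599 ± 46.3 against 0 reads (at least 24540-fold), the gelatinase gene MMP2, at 988 ± 15 against 0 reads (at least 15140-fold), the transcription factor ETS1 (at least 4309-fold) and the membrane protease gene MME, at 953 ± 28.8 against 1 read. FZD2 was 40.7-fold higher (log2 5.35 ± 0.078, SE, adjusted p 5.58e-28).

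Of 14892 genes tested between the control lines, 13219 passed, with 6993 higher and 6226 lower in the libraries labelled FOCUS-GFP. Of 39 hepatocyte genes 37 were lower and 2 higher (camera adjusted p = 7.85e-12, adjusted p = 0.0719 with an estimated correlation), and all 22 liver transcription factors were lower (adjusted p = 2.2e-08, adjusted p = 0.0719 with an estimated correlation). Of 37 epithelial genes 28 were lower and 9 higher (adjusted p = 0.000596, adjusted p = 0.111 with an estimated correlation), with CLDN2 1651-fold lower (counting interval 442 to 97400). Of 28 mesenchymal genes 22 were higher and 6 lower (adjusted p = 0.00231, adjusted p = 0.188 with an estimated correlation), with the repressor gene SNAI2 at least 1809-fold higher. Of 30 YAP and TAZ target genes 26 were higher and 4 lower (adjusted p = 0.000198, adjusted p = 0.188 with an estimated correlation), and of 38 collagens and matrix genes 28 were higher and 9 lower (adjusted p = 0.00269, adjusted p = 0.248 with an estimated correlation). Of 35 interferon response genes 28 were higher (adjusted p = 0.005, adjusted p = 0.208 with an estimated correlation), and of 18 heat shock genes 16 were higher and 0 lower (adjusted p = 0.000596, adjusted p = 0.181 with an estimated correlation). Of 9 Wnt ligands 8 were higher (adjusted p = 0.0214, adjusted p = 0.188 with an estimated correlation), with WNT5A at least 240-fold higher (15.6, against 40.2 in the libraries labelled FOCUS-shFzd2), while 18 of 24 beta-catenin target genes were lower (adjusted p = 0.0142, adjusted p = 0.188 with an estimated correlation).

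Matrix proteases and inhibitors, with 18 of 25 higher, p53 target genes, with 18 of 26 higher, and stellate cell and fibroblast markers, with 8 of 10 higher, also passed (adjusted p = 0.0142, 0.0404 and 0.0214, and adjusted p = 0.188, 0.188 and 0.248 with an estimated correlation). Cholesterol synthesis genes, with 22 of 28 lower, stress response genes, with 27 of 33 lower, STAT3 target genes, with 19 of 28 lower, and histone genes, with 8 of 10 lower, passed as well (adjusted p = 0.000181, 0.000596, 0.00155 and 0.0466, and adjusted p = 0.188 for each with an estimated correlation). The other 14 lists did not pass. Adjusted over the list alone, all these counts were the same. In all, 9 lists were higher and 8 lower of 31 tested, with 0 called with an estimated correlation (6 at an unadjusted p under 0.05) and 29 by fry. There is 1 line of each kind, so the line and its kind cannot be separated. Scaled by library size alone, 7298 genes were higher and 5906 lower, with the median log2 difference at 0.13 in place of 0.07.

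The last comparison asked whether the effect of more against less FZD2 differed between the lines, as the effect in the FOCUS-labelled libraries (GFP minus shFzd2) minus that in the Huh7-labelled libraries (Fzd2 OE minus WT). It differed for 13670 of 15857 genes, with 6810 positive and 6860 negative differences by the edgeR quasi-likelihood test. The libraries labelled FOCUS-shFzd2 and Huh7 Fzd2 OE were nearly alike (r from 0.9952 to 0.996). The contrast therefore largely sets both control groups against a shared profile, and does not by itself show a line-dependent effect of FZD2. For FZD2 the difference was -5.04 on the log2 scale, since the gene moved 15.5-fold in one line and 553-fold in the other. LTBR had a difference of 25.52 (adjusted p 2.26e-35), being lower in both manipulated groups, and KIF1A one of -17.45 (adjusted p 6.66e-37), being higher in both. LAMA4 did not pass (-0.34, adjusted p 0.0891). Scaled by library size alone, 4290 differences were positive and 9557 negative, and the median moved from 0.05 to -0.79.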

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

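The split, regrouping and chromosome window tests were written before their results were seen, and the shares of genes, the marker levels and the percentile of low levels were chosen after the patterns were seen.

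The effect of more against less FZD2 differed between the labelled lines for 13670 genes. Since FOCUS-shFzd2 and Huh7 Fzd2 OE were nearly alike, such differences can arise wherever both control groups depart from them in the same direction. For FZD2 itself the difference was -5.04. Among genes whose signs followed FZD2 in both comparisons it was 1.96 (ANKRD1), -4.92 (BASP1), -0.75 (PCLO), -8.33 (LAMA1) and -0.87 (FLNC). Among genes that went against FZD2 it was 0.95 (GPC3), 0.97 (MBNL3), -0.38 (PLTP), 0.73 (SERPINF1), 1.24 (MGAT4A) and 0.28 (PKDCC). Genes higher in both manipulated groups had -14.94 (SHISA2), -16.12 (PCDH10), -11.97 (FREM2), -10.68 (NYNRIN), -17.45 (KIF1A) and -10.69 (ZNF853). Genes lower in both had 24.69 (PTGR1), 23.86 (SLCO1B3), 25.52 (LTBR), 23.58 (CASP4) and 24.71 (TM4SF1). Values of genes with no or few reads in a group depend on the prior count and are no bounds. In 100 random regroupings within the labelled lines, the highest other count of genes was 7393 against 13670, and 1 grouping, the real one, reached 13670. Other groupings mix unlike libraries, which widens the spread within a group and lowers the count. They do not tell an effect of FZD2 from other differences between the groups.

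Some reads outside the gene counts also differed. Reads in more than 1 gene took 1.41% in the libraries labelled FOCUS-shFzd2 against 1.21% in those labelled FOCUS-GFP, and reads in no gene 7.76% against 7.17%. Reads aligned to more than 1 place took 16.33% in the libraries labelled Huh7 Fzd2 OE against 12.1% in those labelled Huh7 WT, but 15.14% in FOCUS-shFzd2 against 17.5% in FOCUS-GFP. The exact permutation p was 0.1 each, the smallest that 3 against 3 libraries can give.

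The libraries labelled Huh7 Fzd2 OE lacked liver transcripts such as AFP and SERPINA1 and resembled those labelled FOCUS-shFzd2. Of the genes 10-fold apart from Huh7 WT, 90.3% lay within 2-fold of FOCUS-shFzd2, where FZD2 is low. This share restates how near the 2 groups are, so a response of Huh7 cells to FZD2 is left open by it. Another cell line was tested by medians of neighbouring genes along chromosomes, whose SD was 2.12 times its highest shuffled value. This passed the threshold of 1.5 set beforehand for another cell line. The closest pair of groups, which that prediction did not consider, passed it too, at 2.53, so the ratio does not separate unlike from like groups. The SD itself was 0.335 here, 0.358 between the control lines and 0.126 in the closest pair, but expression differences of any origin can widen it, so this test leaves the account open. HEK293T-type cells in both groups may be a source: the median level of 9 kidney and neurofilament genes was 31.6 normalized CPM in FOCUS-shFzd2, 36.9 in Huh7 Fzd2 OE, 3.81 in FOCUS-GFP and 0.0661 in Huh7 WT. The genes were chosen after their levels were seen, SALL1 stood at 40.3 in Huh7 WT, and NEFM, the most abundant, at 41.5 in FOCUS-GFP, so this remains a hypothesis.

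The libraries labelled FOCUS-shFzd2 and FOCUS-GFP differed on the scale of 2 cell lines. Loss of FZD2 in FOCUS cells was set against the libraries with high FZD2: 94.1% of the genes 10-fold lower in FOCUS-shFzd2 were also 10-fold lower in Huh7 Fzd2 OE, a share that also restates how near these groups are and leaves the account open. Another cell line gave a window SD of 2.26 times its highest shuffled value. This also passed the threshold of 1.5, but leaves this account open for the reasons given for Huh7. A genotype at known variant sites, read from the sequences, may separate these accounts, and sequences were not used here.

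Splits of the 6 libraries of a comparison, the real one among them, are too few, at 10, to judge a count. The real grouping gave 13443 genes in the knockdown, 13162 in the overexpression, 13219 between control lines and 8079 between Huh7 Fzd2 OE and FOCUS-shFzd2, and the highest other split gave 0 in each by the edgeR quasi-likelihood test. At an unadjusted p under 0.05 the other splits gave 2 to 8, 0 to 6, 0 to 4 and 80 to 116 genes. For lists the real grouping gave 14, 14, 17 and 9, and the highest other split 12, 14, 15 and 10. The list count of the real grouping was reached by 1 split, the real one, in the knockdown and the control lines, and by 3 splits in the overexpression and the added comparison. In 100 pairs of splits, the counts of opposite (3316) and same (7865) directions were reached by 1 pair, the real one, and the highest other was 0. These pairs combine the same splits, and every other split called 0 genes. Every other pair therefore had to give 0, so the pairs cannot judge these counts either.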

How the results depend on the processing

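Scaling by library size alone and every alternative of the comparison of Huh7 Fzd2 OE with FOCUS-shFzd2 were chosen after results were seen, and the other alternatives were chosen before.

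A test against a fold of 1.5 lowered the counts by construction, to 8214 genes (4190 up, 4024 down) in the knockdown, 8469 in the overexpression, 8501 between control lines and 468 (380 up, 88 down) between Huh7 Fzd2 OE and FOCUS-shFzd2. With an absolute log2 change of at least 0.5 in both fits, 1441 genes went opposite ways and 5076 the same way. The correlation was 0.532 over genes with a mean log2 CPM of at least 3, and 0.5111 to 0.5245 with each library left out in turn, and the cause was not tested. With an estimated correlation camera called 0 lists in the knockdown, 0 in the overexpression, 0 between control lines and 0 in the added comparison, while fry, which tests each list against no change, called 30, 30, 29 and 24. DESeq2 gave 13028, 12719, 12778, 6944 and 13943 genes in the knockdown, the overexpression, the control lines, the added comparison and the interaction. Leaving out each library gave 13269 to 13471, 13045 to 13336, 12931 to 13450, 7047 to 8123 and 13584 to 13756 genes in the same order, and FZD2 at -3.99 to -3.92 and 9.0 to 9.17. Opposite directions ran from 3213 to 3330 and same directions from 7740 to 7930. Lists ran from 13 to 14, 13 to 14, 16 to 17 and 8 to 11. A tally over the alternatives covered 576 gene results and the 54 list results that passed. Of these under alternatives, 7960 and 480 were the same, 60 and 60 were weaker and 0 changed direction. Outside this tally, matrix proteases and inhibitors and TGF-beta target genes in the overexpression, which had not passed, were down by camera and up by fry.

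With the replicate number as a block, 13319, 13107, 13131, 8187 and 13564 genes passed, FZD2 stood at -3.95 and 9.11, 3255 genes went opposite ways and 7792 the same way, r was 0.5209, and lists numbered 14, 14, 17 and 9. Deviations of libraries with the same number had r of -0.146, -0.105 and -0.105 in the knockdown, so the numbers give no pairing.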

Other observations

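The comparison of the libraries labelled Huh7 Fzd2 OE with those labelled FOCUS-shFzd2, its lists, the Frizzled list without FZD2 and the low-level test were chosen after these groups were seen to be the closest pair.

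If both groups were cells of 1 kind, this comparison would show what differs beside high against low FZD2, which stood at 1309 against 6.61 normalized CPM. The YAP target ANKRD1 stood at 46.7 ± 2.08 against 6.25 ± 0.264 (SD, n = 3), 7.6-fold higher (adjusted p 1.54e-17 by the edgeR quasi-likelihood test). HES4, a Notch target, was 4.92-fold, the inhibitor of BMP signalling SMAD6 2.92-fold, and the AP-1 gene JUND 2.72-fold higher. The receptor gene ADGRB1 was 2.97-fold and the stress gene DDIT4 2.7-fold lower. BCYRN1 and RNA45S5, 48.7-fold and 14.1-fold higher, are multi-copy and uncertain. Of 14235 genes, 8079 passed, with 4186 higher and 3893 lower, but 405 differed 2-fold or more, with 320 higher and 85 lower, and 13 differed 10-fold or more, with 7 higher and 6 lower.

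Of 32 immediate early genes 22 were higher and 3 lower (camera adjusted p = 9.13e-05, adjusted p = 0.137 with an estimated correlation). YAP and TAZ target genes, with 20 of 28 higher, and TGF-beta target genes, with 20 of 27 higher, had an adjusted p = 0.00026 each (adjusted p = 0.215 and 0.137 with an estimated correlation). Frizzled receptors, with 7 of 11 higher, FZD2 among them, collagens and matrix genes, with 19 of 32 higher (20 adjusted over the list alone), and Notch pathway genes, with 12 of 26 higher, had 0.00573 each (adjusted p = 0.215, 0.464 and 0.283 with an estimated correlation). Without FZD2, the manipulated gene, 6 of 10 Frizzled receptors were higher (adjusted p = 0.0372, adjusted p = 0.283 with an estimated correlation). Liver transcription factors, with 7 of 14 higher, had 0.0331 (adjusted p = 0.283 with an estimated correlation). Ribosomal protein genes, with 43 of 57 lower, and hypoxia genes, with 23 of 32 lower (24 adjusted over the list alone), had 3.42e-06 and 0.00026 (adjusted p = 0.513 and 0.491 with an estimated correlation). These groups carry different line labels, so FZD2 cannot be separated from the line, the vector or the preparation.

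In the libraries labelled FOCUS-GFP, 138 genes at 20 normalized CPM or more in FOCUS-shFzd2 and under 0.1 in Huh7 WT were all present. Their level was 6.73% of that in FOCUS-shFzd2 at the 5th percentile, 22.5% at the median and 62.4% at the 75th percentile, and 22 of them were as high or higher in FOCUS-GFP, so not all mark FOCUS-shFzd2. A share of RNA of the FOCUS-shFzd2 kind may add to these levels, but SHISA2 and PCDH10 stood at 3.81% and 4.01%, and ADGRB1, the lowest of 9649 genes at 10 or more in FOCUS-shFzd2, at 1.38%. A share that small could not account for the percentile or the median by itself. A smaller share as part of these levels stays open, since this limit rests on few genes, and ADGRB1 itself differed 2.97-fold between the closest groups. Reads exchanged between libraries would act in both directions, and the reverse 5th percentile was 0.0247% over 175 genes, which speaks against exchange as the cause. The percentile replaced another statistic after the values were seen.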
